A study of Homo sapiens with 35 samples.

How the data were processed

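Expression was measured on arrays in sural nerve biopsies of 35 patients with diabetic neuropathy, 18 with progressive and 17 with non-progressive disease at 52 weeks, and the groups were taken from the sample titles. Per the labels' protocols, total RNA was isolated from a segment of each biopsy with an on-column DNase digestion, checked by microfluidic electrophoresis, amplified and hybridized as biotinylated cDNA. A description field that speaks of another organism was not used. The deposited values are array intensities on a linear scale, rounded to 1 decimal, from 2.8 to 14194, and were made with RMA, per the submitters' processing notes. RMA corrects the background, normalizes the arrays to a common distribution and summarizes the probes of a probe set. The array model, the RMA version and any later scaling are not given in the sources used here. Normalization to a common distribution hides a change shared by most genes, and differences of dim genes are understated where background remains in the signal. The table has no detection calls, so no gene could be called absent, and no date or batch, so none was tested.

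The table held 17726 rows. Of these, 16743 were paired with 1 gene symbol, 0 with several, and 983 were unnamed here, and 16724 of the named rows were matched by Entrez number to the RefSeq table of assembly GRCh38.p14, which was used for symbols and for leaving out Y-linked genes. Y-linked genes and XIST (29 named rows) were left out, and where a symbol had more than 1 row the row with the highest mean was kept, which left 16713 genes. All 35 columns were used. Values were put on the log2 scale without a pseudocount.

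Genes were tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3, progressive minus non-progressive, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The array of 1 patient was 1 replicate. Gene lists, 42 in number, were fixed before the data were examined, as were the tests, the main alternatives and the rule for named genes. They covered 17 kinds of cell, 23 pathways and 2 kinds of reference genes. For each list and array the mean over measured members of the log2 value, relative to the gene's mean over all arrays, was taken. Its difference between groups was given with Welch's SE and 95% interval and tested with a two-sided permutation test of 1e+05 relabelings, adjusted over the 42 lists. The third test added the adipocyte list mean as a covariate to the limma fit, for genes outside that list. Correlations between list means left out genes shared by both lists and used permutation tests with 1e+05 resamples. Intervals for slopes on the adipocyte list mean came from 100 bootstrap resamples of the arrays within groups. Some lists share genes, so their shifts are not independent. Plots were made with matplotlib 3.10.9 in Python 3.11.15.

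The rule for named genes took the 12 largest positive and 12 largest negative differences among genes past the threshold. Where fewer passed, all were taken and filled to 5 per direction by the smallest unadjusted p, given as values, and at most 4 members with the smallest p were named for each list. Unnamed rows, rows of several genes, Y-linked genes and XIST were never named.

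Alternatives for the gene test were all rows, the mean over rows, leaving out genes under the median level, quantile normalization again, a common median, an intensity trend with robust variance, a rank-sum test, array weights, the replicate number as a block, a minimum log2 difference of 0.5, and covariates for the first principal component, adipocytes or myelinating Schwann cells. For the lists, limma's camera with a preset correlation of 0.01 or an estimated one, genes under the median level left out, a common median, the median over members, the replicate block and the adipocyte covariate were tried. Dixon's test for single outlying samples was not run, since both groups hold more than 10 samples.

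The gene test was tested on simulated data with the real genes' means and spreads for this comparison, with 50 genes of the 16713 changed at each of 4 sizes. It recovered 30% of the genes changed by 0.25 on the log2 scale, 78% at 0.5, 94% at 1 and 98% at 2, with 12 false calls among unchanged genes. The simulated genes were independent of each other and 200 were changed at once, whereas the real genes are correlated. These rates may therefore be too high for the real data, where few genes passed. The list test was tried on simulated array means with an SD of 0.5 and not on simulated genes. It called 2% of 200 such lists with no shift at an unadjusted permutation p under 0.05. A permutation test of independent values holds its level by construction, so this says little about the real lists. Of 50 lists shifted by 1 it called 100%, but no observed shift was that large, and smaller shifts were not tried.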

Results

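Gene expression was measured in the sural nerve, a sensory nerve of the lower leg, of patients with diabetic neuropathy, with 1 array per patient. The labels call the neuropathy progressive for 18 arrays and non-progressive for 17 arrays, at 52 weeks. The criterion for progression is not given in the sources used here. RNA came from a segment of whole biopsy, so each value mixes Schwann cells, axons, perineurium, vessels, immune cells and the fat around the nerve. The median intensity per array was 147.4 ± 1.63 (SD, n = 18) in the progressive group and 147.7 ± 2.95 (SD, n = 17) in the non-progressive group. The mean correlation of an array with the others lay between 0.969 and 0.985, and 0 of the 595 pairs of arrays held identical values. The number of arrays limits the precision, and the median half-width of the 95% interval of a gene's difference was 0.17 on the log2 scale.

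The first comparison asked which genes differed between nerves with progressive and non-progressive neuropathy. ADRA1B, which encodes the alpha-1B adrenergic receptor for noradrenaline and adrenaline, was the 1 gene of 16713 past the threshold, and it was higher in the progressive group. Its log2 value was 3.92 ± 0.10 (SD, n = 18) in progressive and 3.66 ± 0.13 (SD, n = 17) in non-progressive nerves, a difference of 0.26 (SE 0.04, 95% interval 0.17 to 0.34). On the intensity scale this was 15.1 ± 1.12 against 12.7 ± 1.26, a 1.19-fold difference, and 18 of 18 progressive arrays lay above the non-progressive median. The adjusted p was 0.0224 (limma, two-sided, Benjamini-Hochberg over all genes). The gene was dim, at percentile 16.5 of the mean levels of all genes. Leaving out 1 array at a time gave adjusted p-values from 0.000814 to 0.0560, and for 10 of the arrays the removal of that array alone raised it above the 0.05 threshold. With array weights, with the replicate number as a block or without the 2 arrays least correlated with the others, its adjusted p was 0.125, 0.529 and 0.0913. The replicate number does not pair the patients, so the block is no part of the design.

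No gene was called lower in the progressive group by limma. At an unadjusted p under 0.05, limma gave 751 genes, 444 higher and 307 lower in progressive nerves, where about 836 would be reached with no difference between the groups. The second smallest adjusted p was 0.950. For 98.6% of the genes the 95% interval excluded a difference of 1 or more on the log2 scale in either direction. The estimate itself was 1 or more in size for 13 genes. The share counts dim genes, whose differences may be understated, so it does not exclude such changes in them.

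The genes with the next smallest unadjusted p are given as values, since none passed the adjusted test. Among those with a positive difference, VSNL1, a neuronal calcium sensor, had a difference of 0.77 (SE 0.18), and OLR1, the scavenger receptor for oxidized low-density lipoprotein, had 0.63 (SE 0.17). RNF128, an E3 ubiquitin ligase, had the difference 0.81 (SE 0.22), and PLD4, a phospholipase D family member of myeloid cells, had 0.36 (SE 0.10). Among those with a negative difference, the scaffold protein gene STRN had -0.39 (SE 0.09) and the antisense transcript ST7-AS1 had -0.56 (SE 0.16). ERO1B, an oxidase of the endoplasmic reticulum, had -0.58 (SE 0.17), the casein kinase gene CSNK1D had -0.20 (SE 0.06), and the uncharacterized LOC145845 had -0.18 (SE 0.05).

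**Figure D1:**
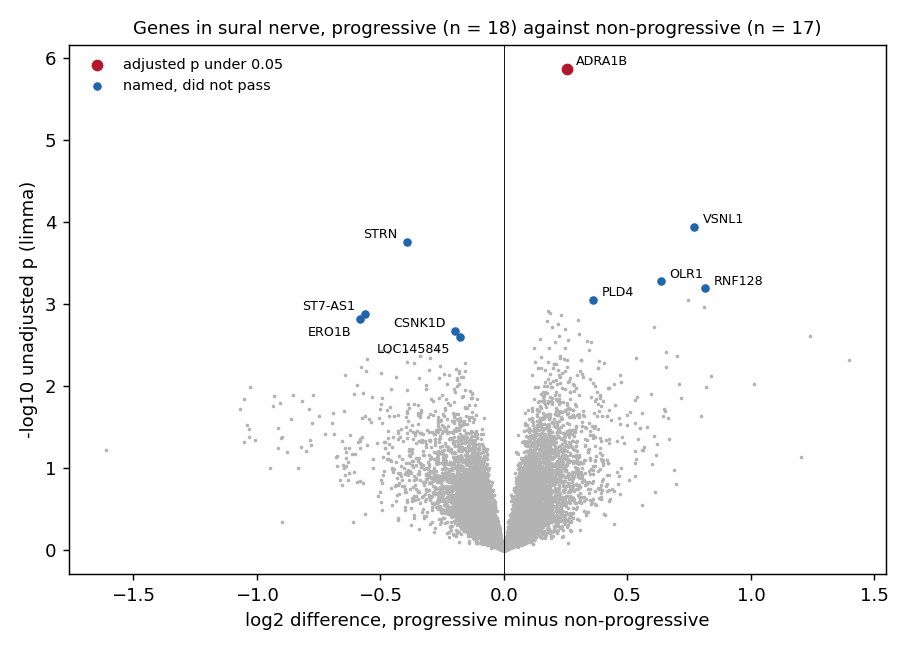
Each point is 1 of 16713 genes, with the log2 difference between 18 progressive and 17 non-progressive nerves on the x axis and minus log10 of limma's unadjusted p on the y axis. ADRA1B (red, difference 0.26) is the gene past the adjusted threshold, and the 9 other named genes (blue) are not past it.

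The second comparison asked whether groups of genes, fixed as cell type markers or pathways, shifted together between the groups. None of the 42 lists passed the adjusted permutation test, where the smallest adjusted p was 0.634, and 1 list had an unadjusted p under 0.05. Of 675 memberships of measured genes in the lists, 0 passed over all genes, and 0 passed when adjusted over the list alone, for every list. Below, a list's shift is the difference of its mean log2 value, progressive minus non-progressive, with the SE in parentheses.

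The most negative shifts belonged to the lists of fat cells and of lipid synthesis. The adipocyte list had a shift of -0.65 (SE 0.33, 95% interval -1.33 to 0.03, permutation p = 0.0595), and 21 of its 22 measured members had a negative difference. Among them, the adipokine genes LEP and ADIPOQ had differences of -1.04 (SE 0.46) and -0.69 (SE 0.30). PLIN1, which coats lipid droplets, had -0.78 (SE 0.34), and GPAM, an acyltransferase of triglyceride synthesis, had -0.82 (SE 0.32). The smallest p of an adipocyte marker, adjusted over the list alone, was 0.142. The list of fatty acid and triglyceride synthesis had a shift of -0.35 (SE 0.17, 95% interval -0.69 to -0.004), with a permutation p of 0.0484 before and 0.634 after adjustment. It had 20 of 21 members with a negative difference, among them MLXIPL, a carbohydrate-responsive transcription factor, at -0.75 (SE 0.31), ME1 at -0.35 (SE 0.15) and THRSP at -1.05 (SE 0.51). The PPAR target list, of genes driven by lipid-activated nuclear receptors, had a shift of -0.23 (SE 0.12, p = 0.0668), with 18 of 22 members negative, such as SCD at -0.82 (SE 0.41) and CD36 at -0.53 (SE 0.29). With the adipocyte list mean of each array as a covariate, the synthesis list had a shift of -0.04 and the PPAR list 0.001. Of their measured members, 18 of 21 and 18 of 22 lie outside the adipocyte list, and THRSP and CD36 are in it. Part of this fall may thus be built in. Fatty acid oxidation (-0.04, SE 0.05), cholesterol biosynthesis (-0.04, SE 0.06) and insulin signalling (-0.02, SE 0.04) had shifts smaller than their errors. IRS2, an adaptor of the insulin receptor, had the smallest p of the insulin list, with a difference of -0.20 (SE 0.07).

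Lists of the nerve itself had positive shifts that did not pass. Repair Schwann cell genes, which mark Schwann cells after nerve injury, had a shift of 0.13 (SE 0.07, permutation p = 0.0556), with 9 of 12 members positive, and of 0.05 (p = 0.289) with the median over members in place of the mean. In that list OLIG1 had a difference of 0.70 (SE 0.23) and JUN, a driver of the injury response, 0.19 (SE 0.07), and the smallest p adjusted over the list alone was 0.0513. Axonal and neuronal transcripts had a shift of 0.14 (SE 0.07, permutation p = 0.0755), with 10 members positive and 7 negative, and of 0.05 (p = 0.287) with the median over members. The neurofilament genes NEFM, NEFL and NEFH had differences of 0.82 (SE 0.30), 0.71 (SE 0.26) and 0.25 (SE 0.14), and GAP43, held by both lists, had 0.56 (SE 0.29). Which cells of the biopsy held these transcripts, axons or Schwann cells, was not measured. The smallest p of the axonal list, adjusted over the list alone, was 0.0867. Perineurial markers had a shift of 0.11 (SE 0.07, p = 0.141), with KRT19 at 0.56 (SE 0.23) and SFRP4 at 0.37 (SE 0.16). Myelinating Schwann cell genes had a shift of 0.10 (SE 0.18, p = 0.595), and MBP, of the myelin sheath, had 0.21 (SE 0.13). Non-myelinating Schwann cell genes had 0.09 (SE 0.12, p = 0.472), with the neurotrophin receptor gene NGFR at 0.23 (SE 0.13). With the adipocyte list mean as a covariate, the perineurial shift was 0.01, the myelinating and non-myelinating Schwann cell shifts were -0.07 and -0.04, and the repair Schwann and axonal shifts were 0.11 and 0.10. The lists of neurotrophins and receptors (0.04, SE 0.05) and of axon guidance (0.03, SE 0.03) had shifts within their errors, with GFRA2 at 0.27 (SE 0.10) and SEMA3C at 0.32 (SE 0.11).

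**Figure D2:**
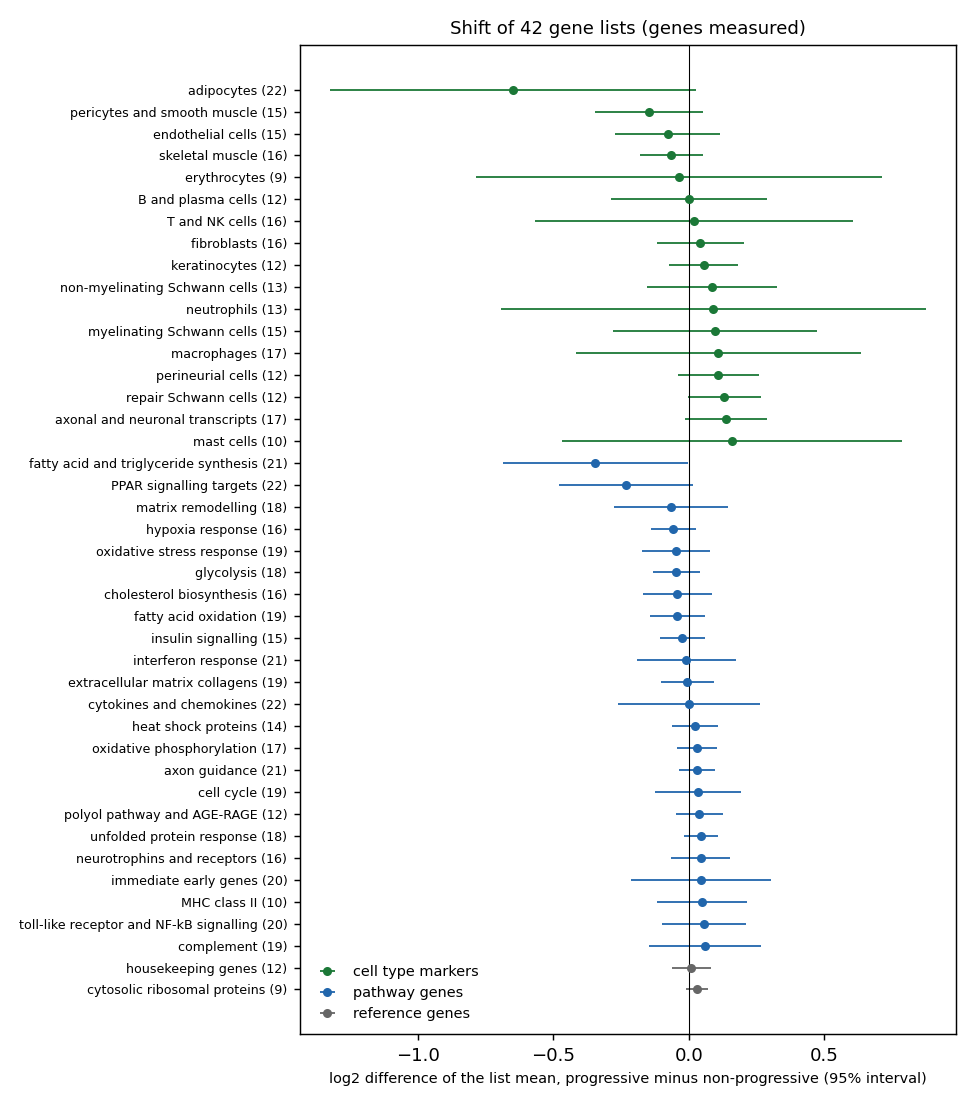
Points are the shifts of 42 gene lists on the log2 scale, progressive (n = 18) minus non-progressive (n = 17), with 95% intervals, and the number of genes measured follows each name. The adipocyte list has the most negative shift, -0.65, and the interval of fatty acid and triglyceride synthesis ends at -0.004.

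Vascular and connective tissue lists differed by less than their errors allow to tell from 0. Pericyte and smooth muscle genes had a shift of -0.15 (SE 0.10, p = 0.143), with 14 of 15 members negative, such as MCAM at -0.27 (SE 0.11) and RGS5 at -0.33 (SE 0.22). Endothelial genes had -0.08 (SE 0.10), with 12 of 15 negative, among them the tight junction gene CLDN5 at -0.19 (SE 0.12). With the adipocyte covariate the endothelial shift was -0.02 and that of pericytes and smooth muscle -0.15. Fibroblast genes had 0.04 (SE 0.08), and 0.10 with that covariate, with the proteoglycan gene OGN at 0.35 (SE 0.14), collagens and laminins -0.005 (SE 0.05) and matrix remodelling genes -0.07 (SE 0.10). Skeletal muscle genes had -0.06 (SE 0.06), with the myosin gene MYH1 at -0.50 (SE 0.21), and keratinocyte genes 0.06 (SE 0.06).

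Immune lists varied widely between arrays, and none of their shifts passed, with or without the adipocyte covariate. Macrophage genes had a shift of 0.11 (SE 0.26) with CD68 at 0.53 (SE 0.30), neutrophil genes 0.09 (SE 0.39), mast cell genes 0.16 (SE 0.31), T and NK cell genes 0.02 (SE 0.29) and B and plasma cell genes 0.001 (SE 0.14). The 95% intervals were correspondingly wide, from -0.69 to 0.87 for neutrophils and from -0.42 to 0.63 for macrophages. Erythrocyte genes, which follow the blood in a biopsy, had -0.04 (SE 0.37). With the adipocyte list mean as a covariate the shifts were 0.38 for macrophages, 0.48 for neutrophils, 0.37 for mast cells, 0.31 for T and NK cells, 0.10 for B and plasma cells and 0.37 for erythrocytes, with adjusted p-values of 0.634 to 0.788. Complement had 0.06 (SE 0.10), MHC class II 0.05 (SE 0.08), the interferon response -0.01 (SE 0.09), cytokines and chemokines 0.0002 (SE 0.13), and toll-like receptor and NF-kB signalling 0.06 (SE 0.08). With the covariate these were 0.15, 0.09, 0.03, 0.13 and 0.11.

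For the lists of energy metabolism and stress the 95% intervals included 0. Oxidative phosphorylation had a shift of 0.03 (SE 0.04), with SDHC, a subunit of succinate dehydrogenase, at 0.17 (SE 0.06). Glycolysis had -0.05 (SE 0.04), with the hexokinase gene HK2 at -0.65 (SE 0.32), and the polyol pathway with AGE-RAGE genes had 0.04 (SE 0.04), with GLO1, which detoxifies methylglyoxal, at 0.09 (SE 0.04). The oxidative stress response had -0.05 (SE 0.06), the hypoxia response -0.06 (SE 0.04), the unfolded protein response 0.04 (SE 0.03) and heat shock proteins 0.02 (SE 0.04). Immediate early genes had 0.05 (SE 0.13) and cell cycle genes 0.03 (SE 0.08). The reference lists, housekeeping genes and cytosolic ribosomal proteins, had 0.01 (SE 0.04) and 0.03 (SE 0.02).

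**Figure D3:**
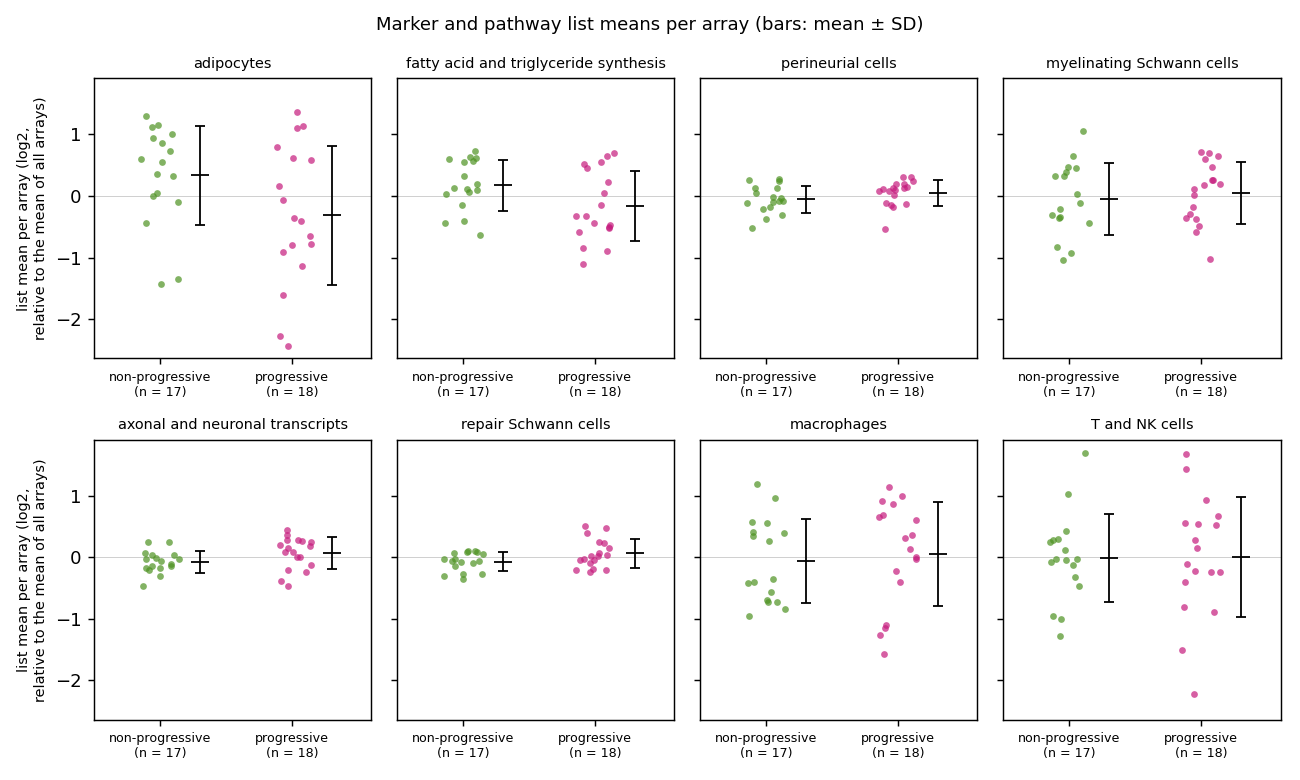
Each point is the mean log2 value of a gene list in 1 array, relative to the mean of all arrays, for 17 non-progressive (left) and 18 progressive (right) nerves, with bars for the mean ± SD. The groups overlap in all 8 lists, and the adipocyte mean has an SD of 1.13 in progressive and 0.81 in non-progressive nerves.

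The third comparison asked which genes differed once the adipocyte list mean, taken as a stand-in for the fat content of each biopsy, was added as a covariate. ADRA1B was again the 1 gene past the threshold, of 16691 genes outside the adipocyte list, with a difference of 0.26 (SE 0.05, 95% interval 0.17 to 0.36) and an adjusted p of 0.0470 in limma. At an unadjusted p under 0.05 the fit gave 923 genes, 480 higher and 443 lower in progressive nerves. None of 5 changes of the processing, chosen after the data had been seen, kept a gene past the threshold in this fit.

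The adipocyte list mean itself went with many genes across arrays. In the same fit, 1324 genes had a positive and 1337 a negative slope on it past the adjusted threshold. Among fatty acid and triglyceride synthesis genes outside the adipocyte list, 14 of 18 had such a positive slope, as had 12 of 17 macrophage genes, 11 of 16 T and NK cell genes and 7 of 9 erythrocyte genes. Negative slopes past the threshold were found for 8 of 12 perineurial, 6 of 13 non-myelinating Schwann cell and 5 of 15 myelinating Schwann cell genes, with no positive one in these lists.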

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

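The removal of the 2 arrays least correlated with the others, and all 5 alternatives of the adipocyte-adjusted test, were chosen after the data had been seen. The count of 1 gene (limma, 751 at an unadjusted p under 0.05) held with all rows, the mean over rows, repeated quantile normalization, a common median, an intensity trend, a rank-sum test and the covariates for adipocytes and myelinating Schwann cells. The count was 0 with genes under the median level left out (380 unadjusted) and with a minimum log2 difference of 0.5, since ADRA1B is dim and its difference is smaller than that. It was also 0 with array weights (1149 unadjusted), with the replicate number as a block (861 unadjusted) and without the 2 arrays (828 unadjusted), and for these the cause was not tested. ADRA1B's difference was then 0.23, 0.26 and 0.23, and over its 12 alternatives with a test its adjusted p ranged from 0.0170 to 0.529, past the threshold in 9. Several of the 9 could change little. The mean over rows left its adjusted p at 0.0224, all rows left its difference at 0.26, and repeated normalization acts on arrays already normalized. With the first principal component of group-centred values as a covariate the count was 2, ADRA1B and VSNL1. That covariate by construction leaves the differences as they are and narrows the residual spread. The replicate numbers are patient numbers of different patients and do not pair the arrays. The block left out the progressive array without a counterpart and fitted a term for each number. That costs degrees of freedom and can raise p with no change in the difference. Same-numbered arrays deviated from their group means with correlations of -0.18 to 0.44 (median 0.004), and 6 of 17 pairs were over 0.1.

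The adipocyte-adjusted count was 0, in place of 1, with an intensity trend (927 unadjusted), genes under the median level left out (464), a common median (924), the replicate block (1060) and without the 2 arrays (961). Camera with its preset correlation called 4 lists in place of 0: adipocytes (shift -0.65, adjusted p = 2.3e-12), fatty acid and triglyceride synthesis, PPAR targets, and pericytes and smooth muscle. With an estimated correlation it called 0, with adjusted p = 0.808 for adipocytes. The estimated correlations of these lists' members were 0.74, 0.47, 0.22 and 0.37, in the same order, far above the preset 0.01. The preset p-values are therefore too small. The other list alternatives called 0, and signs changed in 21 of 331 combinations of list and setting, 12 of them with the adipocyte covariate. Signal over background is not given per gene, so how far dimness limits ADRA1B is open.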

Other observations

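The tests of the adipocyte mean against reference genes, of the slopes of axonal, repair Schwann cell and level-matched genes on it, the bootstrap intervals and the removal of NEFL and NEFM were chosen only after the results were seen. Across the 35 arrays the marker lists of the nerve's cell types moved in blocks. Of 136 relations between the 17 cell type lists, 30 positive and 6 negative ones passed Benjamini-Hochberg adjustment of Pearson's r, and 1e-05 is the smallest p the permutations can give. Markers of macrophages and mast cells rose together (r = 0.82, rho = 0.83, permutation p = 1e-05 for each, adjusted p = 0.000136 and 0.000194, n = 35), and r was 0.78 without the 2 arrays farthest from the median. Fibroblast and mast cell markers did so as well (r = 0.80, rho = 0.81, both p = 1e-05, 0.79 without 2 arrays), as did T and NK cell markers with erythrocyte genes (r = 0.82, rho = 0.77, both p = 1e-05, 0.78 without 2 arrays). Macrophage and neutrophil markers had r = 0.67 (rho = 0.66, p = 1e-05 and 2e-05), with 0.95 in progressive and 0.24 in non-progressive nerves, and the difference between these was not tested.

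The spread of a list mean between arrays was wider in the progressive group for 29 of the 42 lists. None of these differences in spread passed the adjusted permutation test, where the smallest adjusted p was 0.389, for the unfolded protein response. At an unadjusted p under 0.05 the cytokine and chemokine list (SD 0.46 against 0.28) and toll-like receptor and NF-kB signalling (SD 0.27 against 0.17) also had wider spreads in progressive nerves. For the first 5 principal components a difference between the groups, tested on components of values not centred by group, did not pass, with permutation p-values from 0.146 to 0.564. The first component held 18.6% of the variance. It went with the adipocyte list mean (absolute r 0.84), with oxidative stress (0.84) and PPAR genes (0.83), and also with matrix remodelling (0.81), fatty acid and triglyceride synthesis (0.79), cytokines and chemokines (0.78), T and NK cells (0.76), neutrophils (0.73), macrophages (0.72) and erythrocytes (0.72). Among the 200 most variable genes were 14 of 22 adipocyte and 10 of 13 neutrophil markers, and the list means of neutrophils and erythrocytes varied more between arrays within the groups (SD 1.14 and 1.10) than that of adipocytes (SD 0.99).

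The call of ADRA1B was weighed against chance and against fat in the biopsy. Of 100 splits of the arrays into groups of the same sizes, the real one included, 3 called at least 1 gene, which is under 5. This asks only whether any gene passes, so it restates the adjusted p of 0.0224 and excludes chance no more firmly than that. The highest other split called 120 genes, and what that split followed was not examined. With the adipocyte mean as a covariate, 102% of the difference was left (0.26, SE 0.05), which argues against differing amounts of fat, as far as that mean measures fat, as its cause. Loss of the call without any one of 10 arrays, and its low level, stay open, so that a higher level of this adrenergic receptor in progressive nerves is a hypothesis.

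The fat content of the biopsies is a candidate source of part of the variation along the first principal component, beside blood and immune cells, whose markers went with the same component. The adipocyte list mean ran against perineurial markers (r = -0.73, rho = -0.81, both permutation p = 1e-05, adjusted p = 0.000136 and 0.000194, n = 35, r = -0.71 without 2 arrays, -0.79 in progressive and -0.62 in non-progressive nerves). Of 40 perineurial, myelinating and non-myelinating Schwann cell markers, 90% had a negative slope on it (36 genes, 95% interval 85.0% to 92.5% over 100 bootstrap resamples of the arrays). Of all other genes 56.7% did (51.4% to 57.7%). A mixture of more or less fat would give this for these lists. The adipocyte mean also rose with erythrocyte genes (r = 0.53), macrophage markers (r = 0.49) and T and NK cell markers (r = 0.49). Perineurial markers ran against erythrocyte genes too (r = -0.51). The negative slopes therefore do not single out fat. For axonal and repair Schwann cell genes a dilution by fat stays open, with 10 of 17 and 8 of 12 negative slopes and a median slope of -0.01 in each. Among their 11 members above the median level of all genes 63.6% were negative (bootstrap interval 45.5% to 81.8%), which does not tell whether fat dilutes them. RNA or array quality cannot be told apart from fat content, since the correlations of the adipocyte mean with ribosomal protein genes, -0.18 (95% interval -0.49 to 0.16), and with housekeeping genes, -0.003 (-0.34 to 0.33), leave weak relations open and neither list measures RNA integrity directly. Whether normalization pushes other genes down where fat transcripts are abundant, and so causes the markers' negative slopes, stays open. Genes in no list, matched on level, had a median slope of -0.01, 5.28% of the markers' -0.24 (bootstrap interval 1.26% to 9.73%). Normalization to a common distribution keeps the median gene of a level nearly constant, so a small median slope was largely fixed in advance. No biological explanation was tested.

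The list means of axonal transcripts and of repair Schwann cell genes rose and fell together across arrays (r = 0.73, rho = 0.75, both permutation p = 1e-05, adjusted p = 0.000136 and 0.000194, n = 35, 0.74 without 2 arrays, 0.73 in progressive and 0.65 in non-progressive nerves). The gene held by both lists, GAP43, is left out of this value, and the 95% interval of 0.52 to 0.85 for r = 0.728 argues against a shared gene as the cause. With the means of the myelinating and non-myelinating Schwann cell lists and of the adipocyte list held fixed, the partial r was 0.63 (95% interval 0.36 to 0.80). This argues against the content of those Schwann cells and of fat, as far as those lists measure it, as the whole cause. The content of repair Schwann cells could not be held fixed, since their list is itself part of the relation, so a shared source in them stays open. A partial r without NEFL and NEFM was not computed. The relation leans on NEFL and NEFM, without which r was 0.39 (permutation p = 0.0205, 14 genes left). These 2 had the highest r of the axonal members and were picked from the same data, so part of this fall was built in. With the repair list mean, NEFM had r = 0.82, NEFL 0.71, TUBB3 0.52, TAC1 0.39 and STMN2 0.25. Other axonal members had lower values, such as NEFH at 0.14, PRPH at 0.05, INA at 0.02, SYT1 at -0.07, UCHL1 at -0.15 and MAP2 at -0.20. The repair list was uneven as well. With the axonal list mean, RUNX2 had r = 0.57, OLIG1 0.53, SOX2 0.49, BDNF 0.32, LIF 0.28 and JUN 0.26. ARTN, TNC, STAT3, SHH and IGFBP2 lay between 0.04 and 0.16. The relation is thus one of some members of each list and not of the whole lists. A link between NEFL and NEFM transcripts and part of the repair Schwann cell list in these nerves may be followed up as a hypothesis that was not tested here. The neurofilament gene NEFH is not part of it, and the lists' shifts with progression did not pass their test.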
